A study of Mus musculus with 10 samples.

How the data were processed

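Cells from mouse lung were profiled by droplet single-cell RNA sequencing after sorting on PDPN (podoplanin, a membrane glycoprotein carried by lung fibroblasts and by some other cells) or on LRRC15 (a membrane protein of matrix-producing fibroblasts). Bleomycin is a DNA-damaging drug that injures the lung and is used in mice as a model of pulmonary fibrosis. The 5 gene expression libraries were PDPN+ cells at day 0 after PBS, PDPN+ cells at day 7, day 14 and day 24 after bleomycin, and LRRC15+ cells at day 24 after bleomycin. Each had a partner library of hashtag antibodies, so that 10 samples are listed in all. A hashtag is an antibody with a DNA barcode that marks the cells of one source before pooling.

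The deposited values are raw UMI counts (distinct molecules counted per gene and cell) in filtered cell-by-gene matrices with 52636 genes and 5 hashtags. Per the labels' protocols, libraries were made with version 3.1 of the 10x Chromium 3' kit. Per the submitters' processing notes, Cell Ranger 6.0.1, bcl2fastq and the mouse build GRCm38 were used; the gene annotation is not given in the sources used here. The deposited counts carry no normalization. Genes are named by the symbols that the deposited feature lists pair with their identifiers, and a symbol's UMIs can include those of overlapping or near-identical genes, which holds for the histone genes and for Saa3, Ccl and H2 family members.

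A note with the deposited hashtag list says that hashtags 6 to 10 are in every library and that each library pools 5 mice. It does not say outright that 1 hashtag is 1 mouse. Each hashtag was taken here as 1 mouse, and every SD and p-value below rests on that reading. Because each day and sort is 1 library, the lane of the instrument and the group cannot be told apart, and p-values measure the spread between mice within a lane.

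Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Hashtag calls used a mixture of 2 Gaussian curves on the log10 counts of each hashtag in each library. Barcodes called for several hashtags were treated as doublets and left out, as were those with none. Several hashtags were called on 4.23%, 7.31%, 14.4%, 7.59% and 12.6% of barcodes passing the filter in the day 0, day 7, day 14, day 24 PDPN+ and day 24 LRRC15+ libraries. Scrublet, run in scanpy 1.11.5, marked at most 4 cells in a library and was taken not to have worked. Doublets of cells from the same mouse remain.

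All barcodes that passed the filter were clustered together on the log of UMIs scaled to 10000 per cell. Those with several hashtags or none were included and left out afterwards. The clustering used 2000 variable genes, 30 principal components, a graph of shared neighbours among 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. A cluster was called X-like from marker lists fixed before the data were examined. For this, at least 3 markers had to be found in at least 10% of its cells and to lead over other clusters by a log2 fold of at least 1. The fibroblast pool held the clusters named fibroblast-like of any kind and the cycling cells with fibroblast markers. Smooth muscle-like, pericyte-like, mesothelial-like, epithelial, endothelial and immune clusters were left out. One contractile cluster (number 4) led with markers of several fibroblast classes and scored highest for smooth muscle. It carried all 6 fibroblast markers and stayed in the pool by an exception that the rule fixed beforehand does not hold. It made up 1654 of the 7513 LRRC15+ pool cells. Classes were compared between groups only where no cluster held more top markers of another class than of its own. The adventitial-like class fell short of that, because cluster 8 had the alveolar marker Inmt among its top 10 genes. Its clusters were therefore compared by number, and values within it are those of cluster 7 alone, the one led by Adh7.

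UMIs were summed over the pool and scaled to CPM (counts per total of 1e+06 UMIs). Ratios are of pooled CPM with 1 CPM added to each side, on the log2 scale, which understates changes of low genes. A gene was counted by size when it had at least 20 CPM in either pool and a ratio of at least 2-fold. Exact binomial intervals at 95% and the floor of 3 counts behind a bound cover counting error only. This description by size was fixed as the main result before the data were examined. So were the gene lists, the naming rule without its exception for cluster 4, and most alternatives. The plan fixed then held no test on mice. It gave the values of hashtags as a range, without a mean, SD or test, because the labels do not name them as animals. The tests on mice, of lists and of shares are additions to that plan, as is every mean ± SD. For the test on mice, counts were summed per mouse over the pool into 25 sums. These were fitted together with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit and glmQLFTest). Genes were called at an adjusted p of 0.05 (Benjamini-Hochberg over all genes tested), and counts of calls also ask for a 2-fold change. The words rose and fell are used for genes with such an adjusted p. Where a value is given as mean ± SD it is the CPM over 5 mice, and adjusted p without another name is edgeR's. Over all genes of the pool the median log2 ratio was 0.15 at day 14 and 0.14 at day 24 against day 0 and nearer 0 in the other main comparisons, and ratios are to be read relative to it.

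Named genes are the 10 with the largest and the 10 with the smallest ratio per comparison among genes with at least 20 CPM in either pool, leaving out mitochondrial, ribosomal protein, haemoglobin, sex-linked and provisional names. To these come 2 to 4 members of each fixed list, those with the largest absolute log2 ratio. Outside this rule, C3 at day 14, Acta2, Spp1 and Cd248 in the LRRC15+ comparison and the genes given within clusters that the rule does not name were chosen after their values were seen. The 18 lists are the sort targets, fibrillar and associated matrix, collagen processing and cross-linking, fibrotic fibroblast, contractile, TGF-beta response, Wnt pathway, inflammatory and chemokine, interferon response, p53 targets, cell cycle, glycolysis, endoplasmic reticulum folding and stress, alveolar fibroblast identity, lipid handling, adventitial fibroblast identity, matrix proteases and inhibitors, and immediate early and dissociation genes. Members with at least 5 CPM in either pool counted as measured. Except for the sort targets, lists were tested against other genes with camera in limma 3.58.1, at its preset correlation of 0.01 and again with a correlation estimated from the data, with p adjusted over the 68 tests of 17 lists in 4 comparisons. Each list's median was also set among 10000 random lists matched on expression.

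Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, leaving out shallower cells. Differences of shares were tested with a two-sided exact permutation test over 5 against 5 mice, whose 252 splits give a smallest p of 0.0079, adjusted over 40 tests. This test leaves out any pairing of mice by hashtag number between the day 24 libraries. The edgeR steps were tested on simulated data with 200 genes changed by known folds. Of those changed 2-fold it called 67, 67, 67 and 66 of 67 in the simulated day 7, day 14, day 24 and LRRC15+ comparisons, and of those changed 1.5-fold 62, 60, 63 and 57 of 66. Of the unchanged genes it called 16 of 12148, 9 of 12132, 12 of 12390 and 9 of 12746. When the simulated sums were redrawn as Poisson counts, the 95% intervals held the ratio of these sums for 95.3%, 95.2%, 95.4% and 95.3% of genes. This checks counting error only, and not the spread between mice or the known folds.

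The labels do not say whether a hashtag number marks the same mouse in several libraries. Between the day 24 PDPN+ and LRRC15+ libraries the deviations of same-numbered sums from their group means correlated at 0.277 to 0.650 across 4259 genes, and every sum correlated best with its own number. No other pair of libraries passed this check, so a fit with the number as a block was made for the day 24 libraries, as an addition after seeing the data. Alternatives also covered scaling, the filters on genes and cells, doublets, the definition of the pool and the weight of cells and mice. Cycling cells, DESeq2 1.42.0 and the thinning depth were covered too. Each hashtag number was also left out of all libraries at once. A value given without a hashtag therefore lacks a mouse in each group compared, and these need not be the same mouse. Python 3.11.15 and R 4.3.3 were used.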

Results

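Lung cells of C57BL/6 mice were sorted as PDPN+ at day 0 after PBS and at day 7, day 14 and day 24 after bleomycin, and as LRRC15+ at day 24, with 5 mice pooled in each library. After filters and hashtag calls the 5 libraries held 3487, 4515, 5539, 6363 and 7528 cells of 1 hashtag each. The fibroblast pools held 3338, 4218, 5292, 6182 and 7513 of these, with median depths of 8920, 8711, 9743, 7407 and 6126 UMIs per cell and median mitochondrial shares of 3.21%, 2.39%, 1.52%, 2.33% and 2.51%. Summed over the pool, a mouse gave between 5529308 and 14307735 UMIs.

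The sorted cells were mostly fibroblast-like at each day. The fibroblast pool made up 95.7%, 93.4%, 95.5% and 97.2% of PDPN+ cells at day 0, 7, 14 and 24 and 99.8% of LRRC15+ cells. Mesothelial-like cells, which line the lung surface and carry PDPN, were 3.097% of PDPN+ cells at day 0, 2.28% at day 7, 1.34% at day 14 and 1.01% at day 24. They were not detected among 7528 LRRC15+ cells, which allows a share of up to 0.0399%. Pericyte-like cells were 0.803% at day 0 and 2.95%, 2.13% and 1.63% at the later days. A mixed cluster with immune markers held 0.0574% of cells at day 0, 1.06% at day 7, 0.397% at day 14 and 0.0314% at day 24. All these shares depend on the sort. Over 5 against 5 mice, the exact permutation p was 0.0079 for pericyte-like cells at each day. For mesothelial-like cells it was 0.0952 at day 7 and 0.0079 at the later days. For the mixed immune cluster it was 0.0079 at day 7 and 0.0238 at day 14, and day 24 did not pass. With a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs) mesothelial-like cells were 1.77% at day 0 and 1.88% at day 7 (exact permutation p 0.794), and their fall at day 14 did not pass (−0.470 points, 0.143), while that at day 24 did (−0.893 points, 0.0079). Pericyte-like cells were 0.422% at day 0 with that filter and the mixed immune cluster 0.644% at day 7.

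The make-up of the fibroblast pool differed widely between day 0 and the bleomycin libraries. Adventitial-like clusters, named from markers of the fibroblasts around vessels and airways such as Pi16 and Clec3b, are compared by number, since cluster 8 had the alveolar marker Inmt among its top genes. Per mouse, cluster 8 made up 31.9 ± 3.42% of the pool at day 0 (SD, n = 5 mice), 0.777 ± 0.621% at day 7, 0.377 ± 0.237% at day 14 and 0.683 ± 0.320% at day 24. Cluster 9 went from 27.65 ± 5.004% to 1.91 ± 1.31%, 0.998 ± 0.855% and 1.245 ± 0.7103%, cluster 12 from 18.0 ± 2.02% to 2.54 ± 0.625%, 0.734 ± 0.442% and 1.03 ± 0.392%, and cluster 7 from 14.1 ± 2.42% to 7.47 ± 1.83%, 3.42 ± 1.84% and 3.57 ± 1.11%. Cluster 16 varied widely between mice, at 1.997 ± 3.28% at day 0 and 3.43 ± 3.19%, 0.593 ± 0.789% and 2.23 ± 2.82% at the later days. Its means were 0.534% at day 0 without hashtag 10 and 0.264% at day 14 and 1.197% at day 24 without hashtag 7. Inflammatory-like cells reached 23.3 ± 3.11% at day 7, and fibrotic-like cells 9.41 ± 2.09% at day 14 and 15.8 ± 1.30% at day 24. Alveolar-like cells were 0.123% at day 0, 9.36% at day 7, 31.4 ± 2.37% at day 14 and 36.1 ± 2.40% at day 24. Their low share at day 0 was not told apart from the naming of cluster 8 or from the sort. In the LRRC15+ library 52.6 ± 8.21% of the pool was fibrotic-like and 0.816% alveolar-like. Clusters and classes are defined in part by genes that respond to the treatment, so their sizes are given as a description. Clustered without the listed response genes, the fibrotic-like share was 0.0296%, 0.646%, 9.77% and 16.9% at day 0, 7, 14 and 24, with 52.9% in the LRRC15+ library. These clusters were still named from the same fibrotic markers, so the shares are not an independent check. Since clusters 8, 9 and 12 held much of the day 0 pool and little of the later ones, ratios over the pool mix the change within a cluster with the change of the clusters, and values within cluster 7, an adventitial-like cluster present at each day, are given beside them.

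**Figure D1:**
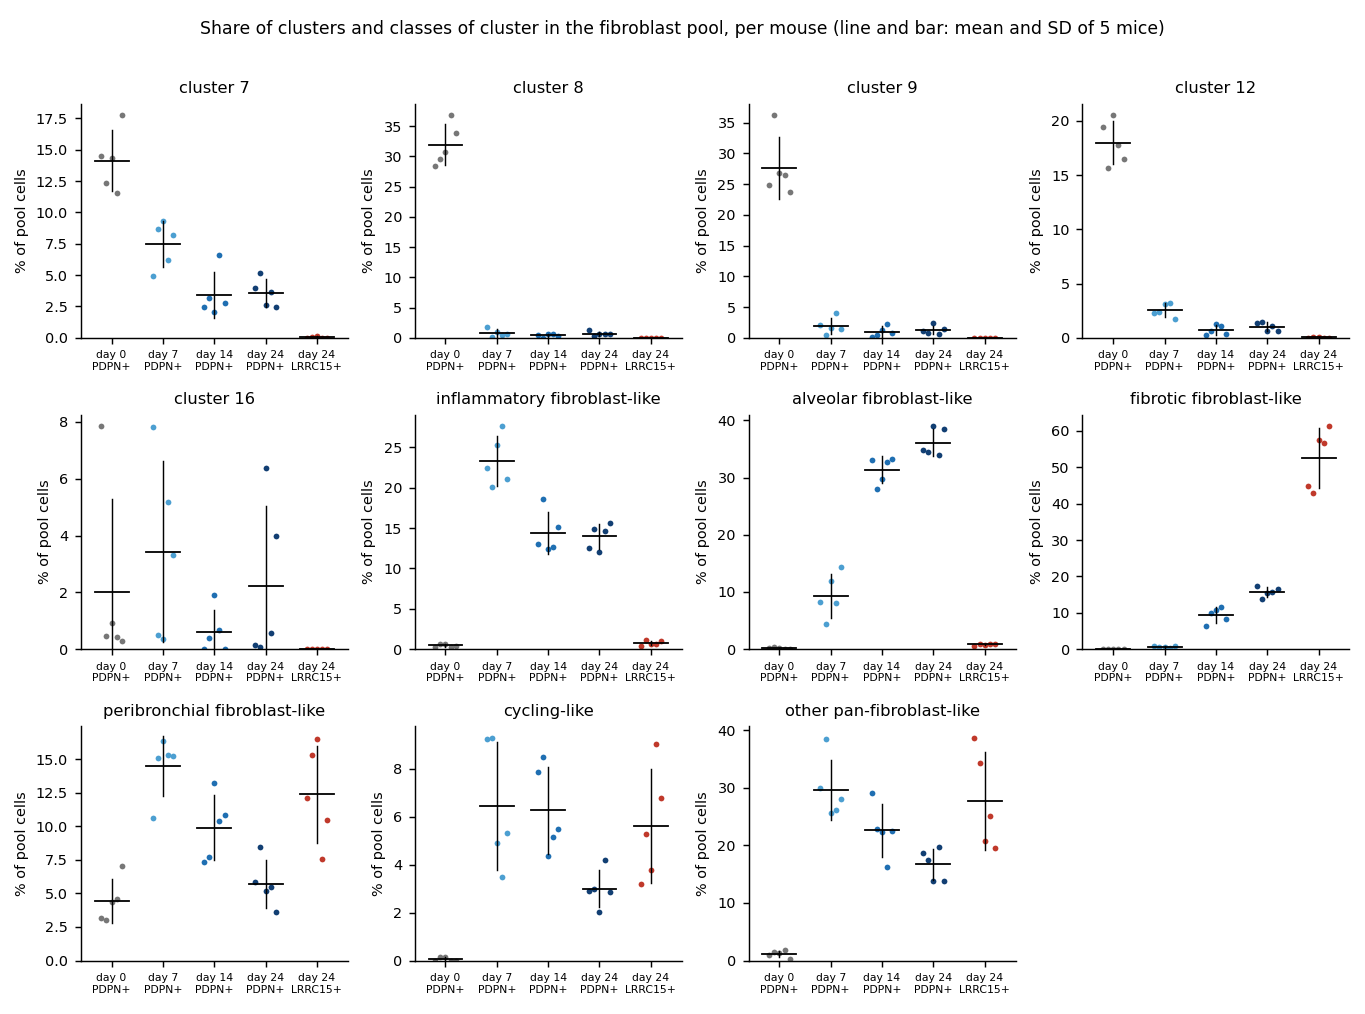
Share of adventitial-like clusters 7, 8, 9, 12 and 16 and of the other classes of cluster in the fibroblast pool (percent of pool cells, vertical axes starting at 0), with 1 point per mouse and the mean and SD of 5 mice as line and bar. Cluster 8 was at 31.9% at day 0 and 0.377% at day 14, and the fibrotic-like share 52.6% in the LRRC15+ library.

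Markers of cells outside the fibroblast pool also differed between groups. Summed over 6 markers each, smooth muscle markers stood at 139.8 ± 62.2 CPM at day 0, 745 ± 102 at day 7, 651 ± 74.5 at day 14, 644 ± 93.6 at day 24 and 2192 ± 299 in the LRRC15+ pool (SD, n = 5 mice). Among the smooth muscle markers, Myh11, Actg2, Lmod1 and Cnn1 are also members of the contractile list. Blood endothelial markers stood at 129.5 ± 13.4, 48.6 ± 8.72, 34.4 ± 4.37, 36.3 ± 4.29 and 10.3 ± 1.48 CPM in the same order. The 17 immune markers stood at 5.49 ± 1.46, 14.4 ± 2.56, 18.9 ± 4.50, 15.9 ± 1.502 and 6.09 ± 0.655 CPM. Mesothelial markers went from 3.23 ± 0.828 CPM at day 0 to 31.4 ± 2.93 at day 24 PDPN+ and were 2.68 ± 0.808 in LRRC15+ cells, and pericyte markers from 52.5 ± 9.20 to 111 ± 9.51 and 147 ± 17.2. Airway epithelial markers were 21.2, 11.3, 12.2, 22.4 and 3.93 CPM. Alveolar type 1 markers were at most 16.5 CPM, alveolar type 2 markers 6.50, Schwann markers 4.36 and lymphocyte markers 0.373 in any group's mean. The means of lymphatic endothelial markers at day 0 (10.1 ± 19.6 CPM) and of erythroid markers at day 7 (14.9 ± 32.8 CPM) had SDs larger than themselves.

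The comparison of day 7 with day 0 asked how PDPN+ fibroblasts differed early after bleomycin. Spp1, which encodes the secreted adhesion protein osteopontin, rose from 1.60 ± 2.62 to 1384 ± 440.5 CPM (n = 5 mice each; log2 ratio 9.10, edgeR log2 fold 9.79 ± 0.473 SE, adjusted p 4.5e-15), and its log2 ratio was 9.90 without hashtag 6. The acute-phase gene Saa3 rose from 4.596 ± 6.95 to 1353 ± 822 CPM (7.79, and 9.15 without hashtag 9), and the siderophore-binding Lcn2 from 1.04 ± 0.702 to 351 ± 262 CPM. The lists of matrix, fibrotic fibroblast, interferon response, p53 and cell cycle genes passed as rising. The contractile list as rising and the adventitial identity list as falling passed only at camera's preset correlation (adjusted p = 0.055 and 0.063 with an estimated correlation). Gsn, which encodes the actin-severing protein gelsolin, fell from 24290 to 3255 ± 680 CPM (log2 ratio −2.88, adjusted p 2.0e-13), and Inmt, a methyltransferase of resting lung fibroblasts, from 2042 ± 115 to 186 ± 66.98 CPM.

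By size, 450 genes were at least 2-fold higher and 463 at least 2-fold lower at day 7, out of 6431. edgeR called 1642 genes higher and 1203 lower of 14167 tested. The 10 largest ratios also held the replication-dependent histone genes Hist1h2ap (6.19), Hist1h1b (5.47) and Hist1h2ae (5.19), the adhesion molecule Chl1 (6.05), the matrix protein tenascin C (Tnc, from 11.2 ± 10.1 to 452 ± 91.8 CPM), haptoglobin (Hp, 5.19) and the chemokine Cxcl9 (5.13), each on the log2 scale and higher in every day 7 mouse than in every day 0 mouse. Without cycling cells Hist1h2ap was at 2.63, Hist1h1b at 1.36 and Hist1h2ae at 1.89. Among the 10 smallest were Bpifa2 (−3.29), the oestrogen sulfotransferase Sult1e1 (−3.06), the angiopoietin receptor Tek (−3.02), Lsamp (−2.87) and Opcml (−2.82) of a family of neuronal adhesion molecules, the basement membrane chain Col4a4 (−2.81), the leptin receptor Lepr (−2.77) and the protease Pcsk6 (−2.77). All of these passed the edgeR test. The log2 ratio of Tnc was 5.88 without hashtag 8.

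Of 20 fibrillar and associated matrix genes, 18 rose at day 7, 1 fell and 1 did not pass (camera adjusted p 1.4e-10, adjusted p = 0.026 with an estimated correlation, and 0.0546 for the latter without hashtag 9). Col12a1, a collagen that coats fibrils, rose from 27.9 ± 5.16 to 157 ± 23.0 CPM (log2 ratio 2.44), Col7a1 from 1.89 ± 0.446 to 10.51 ± 2.31 and elastin (Eln) from 443 ± 45.0 to 1705 ± 532 CPM. Col11a1 was at 8.47 ± 14.7 CPM and its log2 ratio of 2.89 was 1.09 without hashtag 10. Of 11 fibrotic fibroblast genes 9 rose and 1 fell (adjusted p = 0.0052 with an estimated correlation), among them the latent TGF-beta binding protein Ltbp2 (3.22) and Cthrc1, a secreted collagen-associated protein (4.71, and 3.95 without hashtag 10). All 12 contractile genes rose, with smooth muscle actin Acta2 going from 134 ± 49.4 to 1443 ± 267 CPM, Actg2 from 15.6 ± 9.23 to 147 ± 25.2 and Tagln from 178 ± 75.04 to 1552 ± 131. The contractile call was lost with an estimated correlation (camera adjusted p 1.4e-11, adjusted p = 0.055 with an estimated correlation, and 0.0225 for the latter without hashtag 6). Smooth muscle markers stood at 139.8 CPM at day 0 and 745 at day 7 in the same pools. Since Myh11, Actg2, Lmod1 and Cnn1 belong to both sets, this is no separate measure of muscle cells. Of 16 collagen processing and cross-linking genes 10 rose and 3 fell (5 without hashtag 10), led by the prolyl hydroxylase chain P4ha3 (3.23, adjusted p 1.2e-18) and the protease inhibitor Timp1 (2.82), at a camera adjusted p of 0.011 and an adjusted p = 0.26 with an estimated correlation.

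All 12 interferon response genes rose at day 7 (adjusted p = 0.0057 with an estimated correlation). The transcription factor Irf7 rose from 10.8 ± 1.27 to 132 ± 27.9 CPM (log2 ratio 3.48), Cxcl10 by 2.82 and Rsad2 by 3.21, which was 2.62 without hashtag 7 and 3.83 without hashtag 10. Of 16 inflammatory and chemokine genes 9 rose and 2 fell, or 10 and 2 adjusted over the list alone, and the list did not pass (adjusted p 0.089). Immune markers in the same pools went from 5.49 to 14.4 CPM. All 11 p53 targets rose, led by Plk2 (20.2 ± 2.78 to 194 ± 9.65 CPM), Gdf15 (2.37) and the apoptosis gene Bax (1.40), with an adjusted p = 0.045 with an estimated correlation, and 0.0569, 0.068 and 0.0546 without hashtag 6, 7 and 9. All 13 cell cycle genes rose (adjusted p = 0.040 with an estimated correlation, and 0.0573 and 0.0507 without hashtag 9 and 10), and the proliferation marker Mki67 went from 0.622 ± 0.933 to 50.9 ± 10.8 CPM. All 12 adventitial identity genes fell, such as Pcolce2 (1420 ± 143.5 to 206 ± 54.6 CPM), Clec3b (3506 ± 171 to 613 ± 212) and the progenitor antigen Cd34 (−2.21). That call was lost with an estimated correlation (camera adjusted p 2.6e-07, adjusted p = 0.063 with an estimated correlation, and 0.0299 for the latter without hashtag 8). All 12 immediate early and dissociation genes fell too, such as Nr4a1 (−1.29) and Egr1 (−1.08), at a camera adjusted p of 4.6e-04 and an adjusted p = 0.29 with an estimated correlation. Glycolysis had 10 genes up and 2 down, with Eno1 at 1.62 (camera adjusted p 0.045, 0.0776 and 0.0971 for it without hashtag 6 and 10, and adjusted p = 0.54 with an estimated correlation).

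The other lists did not pass at day 7. Of 12 TGF-beta response genes 7 rose and 4 fell (adjusted p 0.18), with the tendon transcription factor Scx at 2.23 and Tgfbi at −1.88. Of 11 Wnt genes 4 rose and 1 fell, with the secreted protein Wisp1 at 3.01 and the antagonist Sfrp1 at 1.82; this list's median was −0.02, its mean 0.48 and its test pointed up (camera adjusted p 0.086, and 0.0473 without hashtag 10). Endoplasmic reticulum genes had 2 up and 4 down of 13, with the chaperone Hspa5 at −1.02, and a median of 0.01 against a mean of −0.13. Alveolar identity genes had 2 up and 5 down of 10, with Npnt at 1.58 and the transcription factor Tcf21 at −1.53. Lipid handling genes had 3 up and 1 down of 8, with the lipid droplet protein Plin2 at 1.55. Matrix proteases and inhibitors had 4 up and 6 down of 14, with Timp3 at −1.68; their median was −0.12 and their mean 0.06. Of the sort targets, Pdpn rose slightly (84.0 ± 8.52 to 104 ± 12.8 CPM, log2 ratio 0.31, adjusted p 0.0087, and 0.0513 and 0.07505 without hashtag 6 and 8) and Lrrc15 was below 5 CPM.

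Within cluster 7, edgeR called 236 genes higher and 226 lower at day 7 of 6149 tested. Irf7 rose there from 9.98 ± 3.12 to 179 ± 58.6 CPM, Cthrc1 from 1.07 ± 0.636 to 79.6 ± 74.6 CPM and the class I antigen gene H2-Q7, chosen after its values were seen, from 3.15 ± 1.44 to 98.1 ± 49.9 CPM. Inmt fell from 2483 ± 126 to 552 ± 285 CPM and Lepr from 315 ± 45.8 to 38.4 ± 28.9. Of list members tested there, 12 of 18 matrix genes, 9 of 10 interferon genes, 6 of 8 contractile genes and 7 of 9 p53 targets rose, and 7 of 10 adventitial identity genes fell. The rise of Saa3 over the pool did not pass within cluster 7 (adjusted p 0.31). Calls in cluster 7 rest on 314 cells at day 7 and 473 at day 0.

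The comparison of day 14 with day 0 asked the same at the middle time point. Spp1 rose to 8370 ± 938 CPM (log2 ratio 11.71, edgeR log2 fold 12.29 ± 0.492 SE, adjusted p 4.3e-17), and the ratio was 12.55 without hashtag 6. Cthrc1 rose from 4.29 ± 1.69 to 387 ± 54.2 CPM, Ltbp2 from 20.5 ± 3.43 to 676.5 ± 51.8 and elastin (Eln) from 443 ± 45.0 to 2762 ± 245. Adventitial genes fell, with Pi16 at 92.6 ± 30.9 CPM against 1130.0 ± 204 and Clec3b at 247 ± 71.8 against 3506 ± 171. Gsn fell from 24290 to 1243 ± 353 CPM and Inmt from 2042 ± 115 to 94.7 ± 23.9.

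By size 616 genes were at least 2-fold higher and 558 lower at day 14, of 6590, and edgeR called 1742 higher and 1595 lower. The largest ratios also held Chl1 (6.13), the growth factor binding protein Igfbp2 (6.01), Hist1h1b (5.88, and 1.45 without cycling cells), the kinesin Kif26b (5.85), Hp (5.66) and Tnc (5.49). For the hyaluronan-binding Cemip and the microfibril gene Fbn2, day 0 had 3 UMIs each. Their ratios of CPM had counting intervals of 194 to 2749 and 168 to 2390. The smallest ratios were those of Lsamp (−4.43), Bpifa2 (−4.22), Sult1e1 (−4.07), Vit (−3.96), the anion transporter Slco2b1 (−3.94), Galnt15 (−3.93), the ferritin receptor Scara5 (359 ± 33.0 to 23.1 ± 4.40 CPM) and Shisa9 (−3.87). All of these passed the edgeR test. Without hashtag 6 Hp was at 6.25, and without hashtag 8 Tnc was at 6.09.

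Of 20 matrix genes 19 rose and 1 fell at day 14 (camera adjusted p 1.7e-17, and adjusted p = 0.0038 with an estimated correlation). Col11a1 rose to 23.1 ± 4.36 CPM (4.24), Col7a1 by 4.04 and Col12a1 to 321 ± 17.0 CPM (3.48). Of 12 fibrotic fibroblast genes 10 rose and 2 fell (adjusted p = 0.0014 with an estimated correlation). Contractile genes had 10 up and 2 not passed, with Tagln at 2047 ± 173 CPM and tropomyosin Tpm1 at 3.16 (camera adjusted p 5.6e-10, adjusted p = 0.077 with an estimated correlation, and 0.0413 for the latter without hashtag 6). Wnt genes had 7 up and 1 down of 12 (camera adjusted p 0.0026, and adjusted p = 0.069 with an estimated correlation), led by Wisp1 (3.12) and Sfrp1 (2.16). The transcription factor Lef1 had 2 UMIs at day 0, and its ratio had a counting interval of 31.4 to 946. Collagen processing genes had 9 up and 3 down of 16, with P4ha3 at 3.76, Timp1 at 2.59 and the lysyl hydroxylase Plod2 at 1.69 (camera adjusted p 0.011, and adjusted p = 0.26 with an estimated correlation). Cell cycle genes had 12 up of 13, with Top2a at 4.84 (camera adjusted p 7.4e-12, and adjusted p = 0.077 with an estimated correlation).

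All 12 adventitial identity genes fell at day 14 (adjusted p = 0.017 with an estimated correlation). All 12 immediate early and dissociation genes fell, with Nr4a1 at −2.05 and Zfp36 at −1.67 (camera adjusted p 6.9e-08, and adjusted p = 0.11 with an estimated correlation), while the median mitochondrial share of pool cells was 3.21% at day 0 and 1.52% at day 14; handling of the cells was not told apart from treatment. Interferon genes had 10 up and 1 down of 12, with Cxcl9 at 4.44 and Cxcl10 at 1.47 (camera adjusted p 0.020, and adjusted p = 0.26 with an estimated correlation). All 11 p53 targets rose, with Plk2 at 2.76 and Gdf15 at 1.95 (camera adjusted p 6.6e-06, and adjusted p = 0.11 with an estimated correlation). The inflammatory list had 4 up and 7 down of 15. Hp and Lcn2 (4.59, and 3.92 without hashtag 10) rose, while the eosinophil chemokine Ccl11 (−3.21) and complement C3 (3198 ± 304 to 643 ± 50.2 CPM) fell; its median was −0.36, its mean 0.38 and its test pointed down (adjusted p 0.70). TGF-beta response genes had 7 up and 3 down of 12, with Scx at 2.92 and Tgfb1 at 2.12. Glycolysis had 8 up and 2 down of 12 with Eno1 at 1.33, endoplasmic reticulum genes 5 up (3 without hashtag 6, 9 or 10) and 5 down of 13 with Pdia6 at 0.81, lipid handling genes 3 up and 1 down of 7 with lipoprotein lipase Lpl at 1.63, alveolar identity genes 3 up and 4 down of 10 with Npnt at 2.32, and matrix proteases 5 up and 6 down of 14, or 5 and 7 adjusted over the list alone, with the stromelysin Mmp3 at −1.81. These lists did not pass. Medians and means differed in sign for alveolar identity genes (0.02 and −0.45) and proteases (−0.07 and 0.03), and the endoplasmic reticulum test pointed down at a median of 0.22. Lrrc15 rose to 10.49 ± 3.19 CPM from 0.766 ± 0.685 (2.73), and Pdpn fell by 0.28 on the log2 scale.

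Within cluster 7 at day 14, 181 genes were called higher and 254 lower. Ltbp2 rose there from 48.0 ± 17.1 to 407 ± 75.03 CPM and Cthrc1 to 43.7 ± 38.3, and Inmt fell to 460 ± 242 CPM, Gsn from 22240 to 6203 ± 1022 and Scara5 by 1.90 on the log2 scale. Spp1 had 116 UMIs there at day 14 and 1 at day 0. Of list members tested in the cluster, 13 of 18 matrix genes and 5 of 6 fibrotic genes rose, 7 of 10 adventitial identity genes fell, and all 12 immediate early genes fell. This cluster had 165 cells at day 14.

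At day 24, the last day sampled, Spp1 stood at 2783 ± 499.8 CPM (log2 ratio 10.11 against day 0, and 10.95 without hashtag 6, adjusted p 4.2e-16) and Cthrc1 at 346 ± 38.1 CPM (6.03). Ltbp2 reached 944 ± 104 CPM (5.46, adjusted p 4.8e-21), the bone morphogenetic protein antagonist Grem1 272.5 ± 47.3 CPM (5.74, and 7.21 without hashtag 8) and Col12a1 395.7 ± 27.4 CPM (3.77). Ibsp, a sialoprotein of mineralised tissue, had 2859 UMIs (56.8 ± 32.6 CPM) and none at day 0, which makes it at least 568.8-fold higher against a floor of 3 counts over the group. Col11a1 rose from 0.300 ± 0.327 to 73.6 ± 12 CPM.

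By size 537 genes were at least 2-fold higher and 476 lower at day 24, of 6568, and edgeR called 1688 higher and 1353 lower. Igfbp2 (6.86), Saa3 (6.16), Hp (6.16) and Kif26b (5.69) were also among the 10 largest ratios, as was Fbn2 with a counting interval of 190 to 2694 around its ratio. The smallest were those of Lsamp (−4.01), Sult1e1 (−3.88), the retinol carrier Rbp4 (431 ± 51.5 to 31.1 ± 11.9 CPM), periplakin (Ppl, −3.69), salivary amylase (Amy1, −3.68), Shisa9 (−3.63), the scavenging chemokine receptor Ackr3 (174 ± 31.4 to 13.4 ± 5.29 CPM), Vit (−3.59), aldehyde oxidase Aox3 (−3.56) and Bpifa2 (−3.54). All of these passed the edgeR test. Without hashtag 7 Sult1e1 was at −4.77, and without hashtag 9 Saa3 was at 7.54.

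Of 20 matrix genes 19 rose at day 24 and 1 did not pass (adjusted p = 0.0038 with an estimated correlation), with Col7a1 at 4.47 and Eln at 2832 ± 336 CPM (2.67). Of 12 fibrotic fibroblast genes 10 rose and 1 fell (adjusted p = 0.0012 with an estimated correlation). Of 12 Wnt genes 10 rose and 2 did not pass (camera adjusted p 5.0e-05, and adjusted p = 0.019 with an estimated correlation), such as Wisp1 (2.76), the stem cell receptor Lgr6 (2.30) and the antagonist Dkk2 (2.99, and 3.90 without hashtag 10). Lef1 had 2 UMIs at day 0, and its ratio had a counting interval of 35.8 to 1078. All 12 adventitial identity genes fell (adjusted p = 0.011 with an estimated correlation), such as Clec3b (−3.24) and Pi16 (−3.02). All 12 contractile genes rose, such as Acta2 (1469 ± 227 CPM, 3.44) and Tagln (3.27), at a camera adjusted p of 1.2e-11 and an adjusted p = 0.055 with an estimated correlation, the latter 0.0231 and 0.0432 without hashtag 6 and 7. Cell cycle genes had 12 up and 1 down, with Mki67 at 34.7 ± 5.21 CPM (camera adjusted p 2.4e-10, and adjusted p = 0.0995 with an estimated correlation). Of 11 p53 targets 9 rose, with Plk2 at 1.77 and Trp53inp1 at 1.26 (camera adjusted p 6.5e-04, and adjusted p = 0.21 with an estimated correlation). Collagen processing genes had 10 up and 2 down of 16, with P4ha3 at 3.56 and Plod2 at 1.71 (camera adjusted p 0.0032, and adjusted p = 0.21 with an estimated correlation). All 12 immediate early genes fell, with Nr4a1 at −1.99 and Atf3 at −1.51 (camera adjusted p 5.5e-06, and adjusted p = 0.21 with an estimated correlation).

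The remaining lists did not pass at day 24. Alveolar identity genes had 5 up and 4 down of 10, with Npnt rising from 53.9 ± 8.35 to 323 ± 32.5 CPM, while Inmt (−3.15), Tcf21 (−1.75) and the sodium channel Scn7a (−1.47) fell. Lipid handling genes had 2 up and 1 down of 7, with Lpl rising from 171.5 ± 38.1 to 655 ± 55.0 CPM and Plin2 by 1.02. Interferon genes had 7 up and 2 down of 12, or 8 and 2 adjusted over the list alone, with Cxcl9 at 3.55 and Isg15 at 0.96. Inflammatory genes had 5 up and 8 down of 16, with Lcn2 at 4.93 and Ccl11 at −2.83, a median of −0.37 and a mean of 0.46. TGF-beta response genes had 7 up and 2 down (4 without hashtag 6) of 12, with Scx at 2.98 and Tgfbi at −1.34. Glycolysis had 7 up and 3 down of 12, or 8 and 3 adjusted over the list alone, with Eno1 at 1.46 and Hk2 at −1.18. Endoplasmic reticulum genes had 5 up (8 without hashtag 8) and 5 down of 13, with Atf4 at −0.84, a median of 0.38 and a test that pointed down. Matrix proteases had 5 up and 7 down of 13, with Mmp3 at −1.92 and cathepsin K (Ctsk) at 1.47. Lrrc15 rose to 20.2 ± 4.92 CPM (3.58), and Pdpn fell by 0.42 on the log2 scale to 62.7 ± 7.54 CPM.

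Within cluster 7 at day 24, where 218 cells were counted, 171 genes were called higher and 189 lower. Igfbp2 rose there from 3.17 ± 2.75 to 129 ± 199 CPM (log2 ratio 4.56, and 3.12 without hashtag 7, where its adjusted p was 0.151), Cthrc1 to 22.1 ± 19.9 (adjusted p 0.026, and 0.148, 0.0539 and 0.0556 without hashtag 6, 7 and 10) and Ltbp2 to 274 ± 130 CPM. Inmt fell to 543 ± 179 CPM and Tcf21 by 1.83 on the log2 scale. Of list members tested there, 17 of 18 matrix genes, 6 of 6 fibrotic genes and 6 of 8 contractile genes rose, and 5 of 10 adventitial identity genes fell. Without hashtag 6, 3 contractile genes rose, and without hashtag 8, 3 adventitial identity genes fell.

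**Figure D2:**
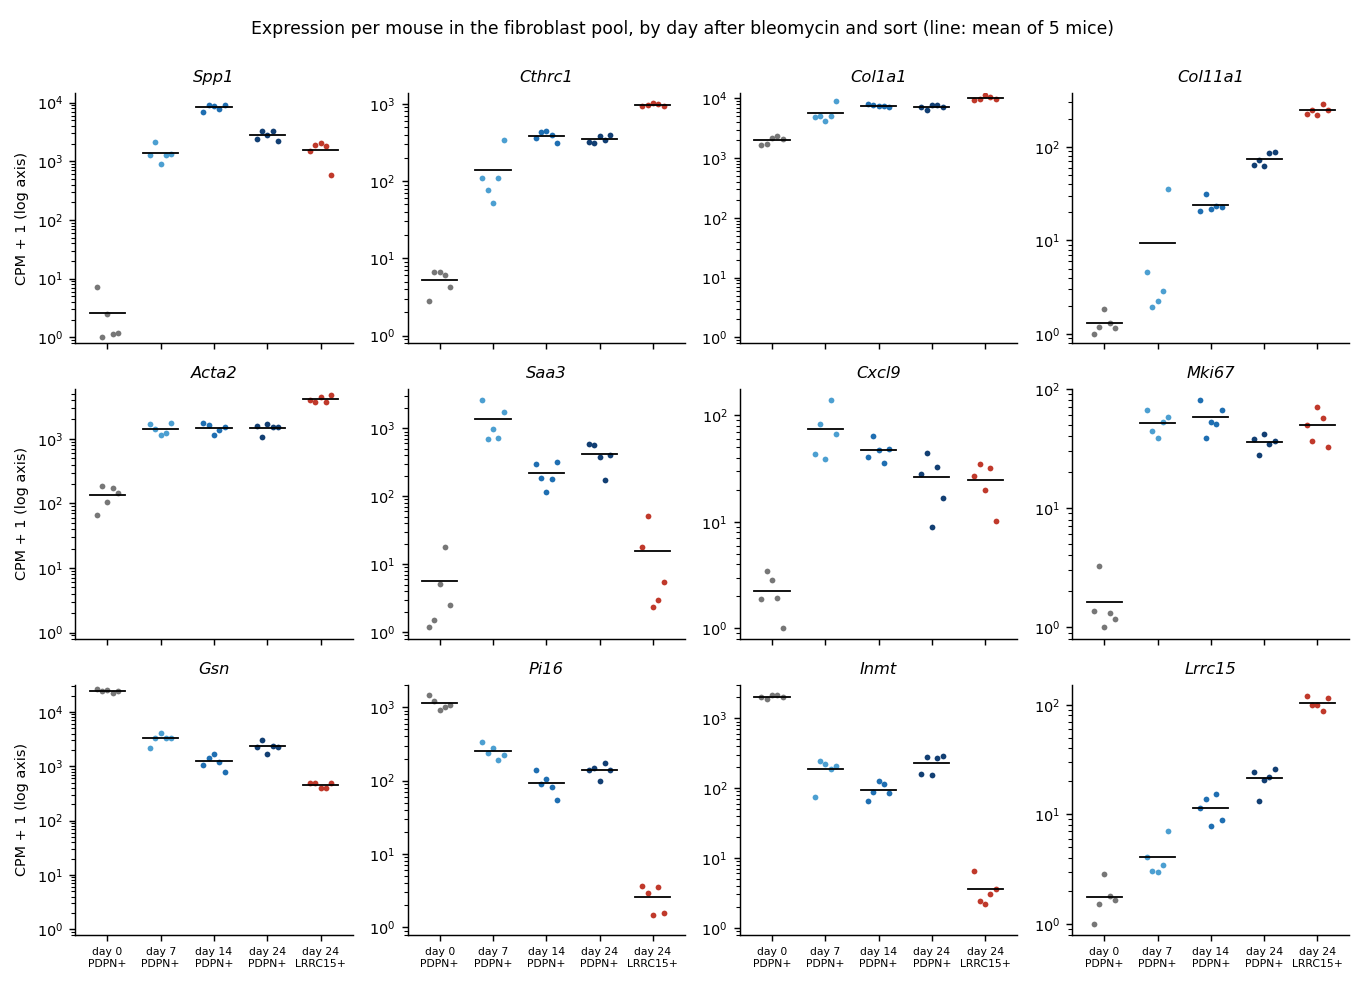
Expression of 12 genes per mouse in the fibroblast pool as CPM plus 1 on a log axis, by day and sort, with 1 point per mouse and a line at the mean of 5 mice. Spp1 was highest at day 14 (8370 CPM), while Col11a1 and Lrrc15 were highest in LRRC15+ cells (245 and 103.7 CPM).

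The steps between bleomycin days were taken as secondary values. From day 7 to day 14, edgeR called 329 genes higher and 416 lower, or 421 and 322 without TMM factors. The collagen-binding Fmod rose from 23.1 ± 4.81 to 182 ± 26.4 CPM (log2 ratio 2.87), the mechanosensitive channel Piezo2 from 24.2 ± 3.52 to 140.4 ± 16.0 (2.46), and C1qtnf3 (2.99), Spp1 (2.62) and thrombospondin Thbs4 (2.58) rose too. The B cell chemokine Cxcl13 fell from 1169 ± 570 to 90.3 ± 54.8 CPM (−3.74), Irf7 from 132 ± 27.9 to 27.7 ± 5.61 (−2.20) and Lcn2 and Saa3 by 2.76 and 2.50 on the log2 scale. Cfd, which encodes the adipocyte product adipsin, had the lowest ratio (−5.25), and 99.34% of its day 7 UMIs lay in 2 cells with adipocyte markers; the ratio was −1.82 without hashtag 10. Of 20 matrix genes 15 rose and 1 fell and of 12 fibrotic genes 7 rose (adjusted p = 0.037 with an estimated correlation for each). The matrix value was 0.0648, 0.0865, 0.0591 and 0.0811 without hashtag 6, 7, 8 and 9, and the fibrotic value 0.0865 and 0.0811 without hashtag 7 and 9. Further, 11 of 12 interferon genes fell (adjusted p = 0.0035 with an estimated correlation). Inflammatory genes had 1 up and 14 down of 16 (camera adjusted p 5.9e-06, adjusted p = 0.14 with an estimated correlation, and 0.0425 for the latter without hashtag 10). At the preset correlation 3 more lists passed. Wnt genes had 4 up of 12 (camera adjusted p 0.0019, and adjusted p = 0.10 with an estimated correlation), adventitial identity genes 9 down of 12 (8.5e-07, and adjusted p = 0.10 with an estimated correlation) and immediate early genes 11 down of 12 (4.4e-06, and adjusted p = 0.27 with an estimated correlation).

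From day 14 to day 24, 132 genes were called higher and 99 lower, or 69 and 65 without hashtag 10. The growth factor binding protein Igfbp3 rose from 76.3 ± 28.6 to 201 ± 9.90 CPM (1.48), the vascular factor Angpt2 by 1.67, Dkk2 by 1.66 and Col11a1 by 1.60. Ibsp (2.41) and the hypertrophic cartilage collagen Col10a1 (2.31) rose as well, and 2 and 3 of 5 day 24 mice lay above all day 14 mice. Ibsp was at 4.74 without hashtag 9 and 1.71 without hashtag 10, its adjusted p was 0.0533, 0.0587 and 0.108 without hashtag 7, 8 and 10, and Col10a1 at 3.80 without hashtag 6. The lipase inhibitor Angptl4 fell from 216.6 ± 51.0 to 68.7 ± 38.6 CPM (−1.72) and Spp1 by 1.60. Of the lists, 7 of 13 cell cycle genes and 7 of 11 p53 targets fell, at camera adjusted p of 3.6e-05 and 5.7e-05 and an adjusted p = 0.35 and 0.21 with an estimated correlation. Without hashtag 6, 9 and 10, 3, 3 and 1 cell cycle genes fell, and without hashtag 7, 9 and 10, 3, 3 and 1 p53 targets. Interferon genes had 5 down of 12, immediate early genes 7 up of 12 and alveolar identity genes 5 up of 10, at camera adjusted p of 6.3e-04, 6.3e-04 and 8.2e-04 and an adjusted p = 0.14, 0.46 and 0.27 with an estimated correlation. Without hashtag 6, 9 and 10, 3, 0 and 2 interferon genes fell, and without hashtag 6, 7, 9 and 10, 1, 2, 3 and 4 immediate early genes rose.

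LRRC15+ cells were compared with PDPN+ cells at day 24 to ask what sets the LRRC15-sorted fibroblasts apart at one time point. Lrrc15 rose from 20.2 ± 4.92 to 103.7 ± 13.2 CPM (n = 5 mice each; log2 ratio 2.29, edgeR log2 fold 2.39 ± 0.181 SE, adjusted p 5.4e-11), as the sort selects. The contractile genes calponin (Cnn1, 79.4 ± 11.2 to 387 ± 64.8 CPM), Actg2 (143 ± 30.4 to 610.2 ± 77.0) and smooth muscle myosin Myh11 (80.4 ± 18.7 to 323 ± 102) rose, as did Cthrc1 (346 ± 38.1 to 967 ± 38.3). Genes of alveolar and adventitial identity and of inflammation fell, such as Inmt (229.5 ± 68.1 to 2.57 ± 1.75 CPM), Pi16 (138.5 ± 26.3 to 1.64 ± 1.04) and C3 (800.3 ± 122 to 21.3 ± 8.07). Smooth muscle markers stood at 644 and 2192 CPM and immune markers at 15.9 and 6.09 CPM in the 2 pools. The smooth muscle markers hold Lmod1 and the Cnn1, Actg2 and Myh11 named above, so they are no separate measure of muscle cells.

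By size 82 genes were at least 2-fold higher and 265 lower in LRRC15+ cells, of 6307, and edgeR called 299 higher and 1046 lower. The largest ratios also held the matricellular Tnn (17.8 to 73.9 ± 15.9 CPM), Sbspon (1.97), C1qtnf3 (1.82), Glipr1 (1.79), Ibsp (56.8 ± 32.6 to 200 ± 44.3 CPM) and Scx (1.75). The smallest held the carboxylesterase Ces1d (105 ± 8.26 to 0.918 CPM), complement C7 (−5.61), Clec3b (−5.54), Hp (−5.45), Limch1 (−4.95), Lcn2 (−4.95) and Scara5 (−4.91). All of these passed the edgeR test, Ibsp at an adjusted p of 0.014, and 0.0648 without hashtag 7.

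All 12 contractile genes rose in LRRC15+ cells, with Lmod1 at 1.53 and Acta2 going from 1469 ± 227 to 4155 ± 463 CPM (camera adjusted p 6.9e-10, adjusted p = 0.077 with an estimated correlation, and 0.0231 for the latter without hashtag 6). Of 12 fibrotic fibroblast genes 9 rose and 1 fell, with Grem1 at 844 ± 70.4 CPM (1.63), Aspn at 1.37 and Spp1 at −0.80 (camera adjusted p 0.0043, adjusted p = 0.11 with an estimated correlation, and for the latter 0.0256 with the hashtag number as a block and 0.0393 without hashtag 8). The fall of Spp1 had an adjusted p of 0.0741 without hashtag 9. Of 20 matrix genes 14 rose and 3 fell (1 without hashtag 6), or 15 and 4 adjusted over the list alone. Col11a1 rose from 73.6 ± 12 to 245 ± 25.1 CPM, Col8a1 by 1.32 and Thbs2 by 1.12, while Eln fell from 2832 ± 336 to 1283 ± 319 CPM (camera adjusted p 0.0011, and adjusted p = 0.22 with an estimated correlation). Collagen processing genes had 10 up and 1 down of 17, with P3h2 at 1.55 and Adamts2 at −0.87 (camera adjusted p 0.0013, and adjusted p = 0.17 with an estimated correlation). Glycolysis had 10 up and 1 down of 12, with the lactate exporter Slc16a3 at 1.05 (camera adjusted p 0.0010, and adjusted p = 0.27 with an estimated correlation). Cell cycle genes had 8 up of 13 (5 without hashtag 8, 3 without hashtag 9), or 10 adjusted over the list alone, with Birc5 at 0.91 (camera adjusted p 0.023, 0.0714 for it without hashtag 9, and adjusted p = 0.54 with an estimated correlation). TGF-beta response genes had 6 up and 2 down of 12, with Tgfbi at 1.34 and Ankrd1 at 1.33 (camera adjusted p 0.022, and adjusted p = 0.26 with an estimated correlation).

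All 10 alveolar identity genes fell in LRRC15+ cells (adjusted p = 0.0012 with an estimated correlation). Of 12 adventitial identity genes 11 fell, with Cd34 at −3.67, and Cd248 rose (adjusted p = 0.0014 with an estimated correlation). The rise of Cd248 had an adjusted p of 0.028, and 0.0652, 0.0687, 0.054 and 0.0976 without hashtag 6, 8, 9 and 10. Of 16 inflammatory genes 13 fell, or 14 adjusted over the list alone, with Saa3 at −4.84, and −5.91 without hashtag 7 (adjusted p = 0.011 with an estimated correlation). Interferon genes had 5 down of 12 (10 with the hashtag number as a block), with Ifi27l2a at −1.72 (camera adjusted p 0.026, and adjusted p = 0.26 with an estimated correlation), and immediate early genes 8 down of 12 (5 without hashtag 9), or 9 adjusted over the list alone, with Atf3 at −0.93 (camera adjusted p 0.017, and adjusted p = 0.52 with an estimated correlation). Of 13 matrix proteases 1 rose and 5 fell (4 and 7 with the hashtag number as a block), with Mmp3 going from 200.6 ± 34.7 to 7.84 ± 3.43 CPM, and of 11 p53 targets 1 rose and 6 fell, with Gdf15 at −1.42. These 2 lists had camera adjusted p of 0.157 and 0.144, and 0.0465 and 0.0402 with the hashtag number as a block, where they did not pass with an estimated correlation (adjusted p = 0.29 and 0.38). Wnt genes (4 up and 2 down of 12, or 5 and 2 adjusted over the list alone and 9 and 2 with the block, with Sfrp1 at −1.29), endoplasmic reticulum genes (3 down of 13, or 3 up and 6 down with the block, with Ddit3 at −0.67) and lipid handling genes (1 up and 3 down of 6, with Fabp5 at 1.32) did not pass. Pdpn fell from 62.7 ± 7.54 to 39.7 ± 4.57 CPM (log2 ratio −0.62, adjusted p 1.1e-05).

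**Figure D3:**
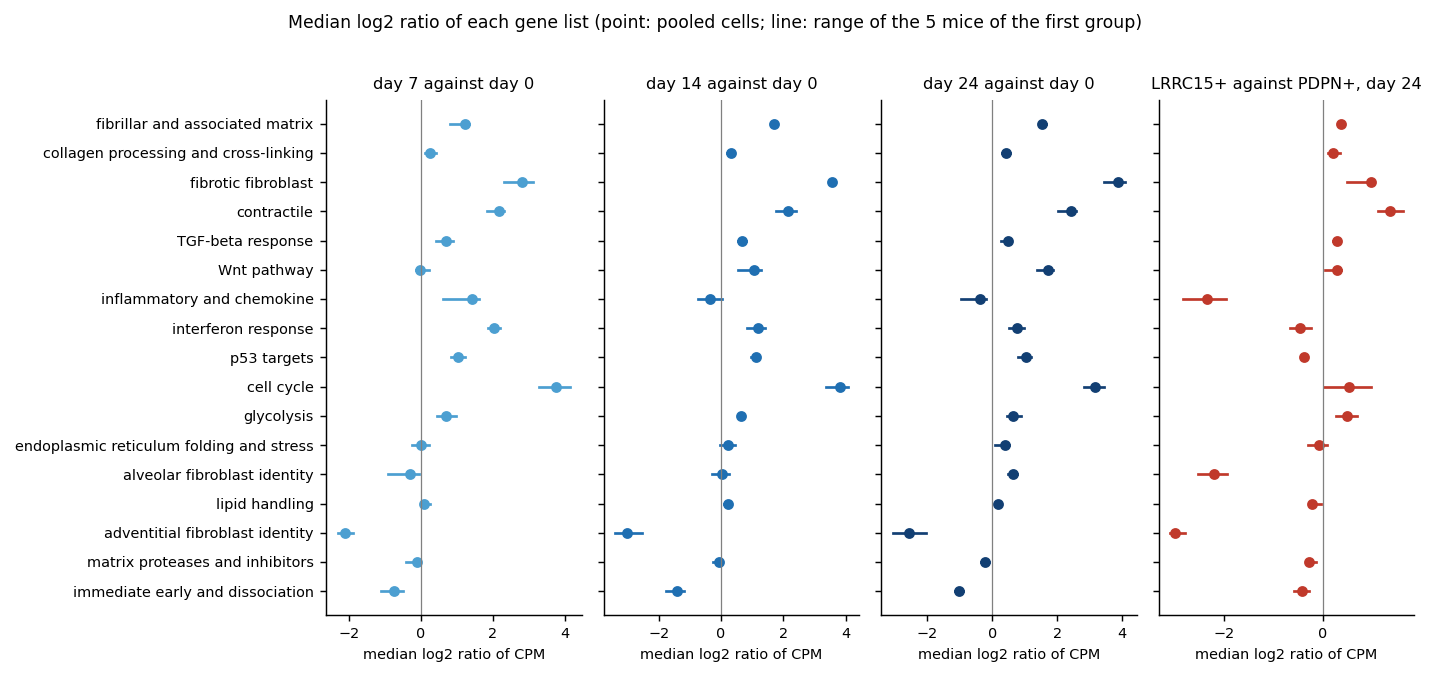
Median log2 ratio of CPM for each gene list in the 4 comparisons, with a point for the pooled cells and a line for the range when each of the 5 mice of the first group is taken alone. The fibrotic fibroblast list had medians of 2.80, 3.55 and 3.86 at day 7, 14 and 24 against day 0 and 0.96 for LRRC15+ against PDPN+ cells.

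Within the fibrotic-like class (clusters 1 and 5, 3965 LRRC15+ and 978 PDPN+ cells at day 24), edgeR called 0 genes higher and 24 lower by at least 2-fold of 10089 tested. The 24 were 15, 37 and 14 without hashtag 7, 8 and 9, and 3 genes were called higher without hashtag 8. At an unadjusted p under 0.05 and 2-fold there were 3 and 37. With no minimum fold edgeR called 49 and 101. Fitted on the 2 day 24 libraries alone, of 10745 tested, it called 0 and 25 by at least 2-fold and 50 and 90 of any size, and with the hashtag number as a block 4 and 44 by at least 2-fold and 662 and 620 of any size. Lrrc15 rose from 43.8 ± 8.54 to 81.2 ± 9.47 CPM (log2 ratio 0.90, adjusted p 0.011, and 0.122 and 0.068 without hashtag 7 and 10) and Tnn from 46.3 ± 10.8 to 71.5 ± 13.1 (0.67, adjusted p 0.032, and 0.0639, 0.168 and 0.196 without hashtag 6, 7 and 9). Limch1 fell from 56.4 ± 26.4 to 11.6 ± 5.37 CPM, C3 from 22.8 ± 11.8 to 5.08 ± 1.63 and Col28a1, chosen after its values were seen, from 19.3 ± 2.17 to 4.71 ± 0.773. Of 12 contractile genes tested there 12 did not pass, of 12 fibrotic genes 11 did not, and of 20 matrix genes Eln alone passed and fell (1506 ± 610.1 to 783 ± 176 CPM; adjusted p 0.031, and 0.0852, 0.161, 0.144 and 0.0825 without hashtag 6, 7, 9 and 10). With the block, 8 contractile genes rose, 5 fibrotic genes rose and 1 fell, and 5 matrix genes rose and 5 fell. Cthrc1, Lrrc15, Postn, Grem1, Tnc, Ltbp2 and Adam12 of the fibrotic list also name the class. A lack of difference in them is therefore partly built in, and Lrrc15 is the sort target. In peribronchial-like cluster 3 the 24 lower genes lost a median of 1.12 times the UMIs per cell that they lost in the fibrotic-like class.

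Shares of pool cells with a UMI were compared after thinning to 2000 UMIs, which left out 204, 78, 108, 155 and 66 shallower cells. Lrrc15 was found in 0.128%, 0.459%, 1.33% and 2.22% of PDPN+ pool cells at day 0, 7, 14 and 24 and in 15.3% of LRRC15+ cells, or 0.390%, 1.52%, 4.20%, 5.50% and 32.7% unthinned. Cthrc1 was found in 0.734%, 8.26%, 24.5%, 22.7% and 57.9% in the same order (2.43%, 18.8%, 41.4%, 36.0% and 74.3% unthinned). Acta2 was found in 8.49%, 41.6%, 47.1%, 47.2% and 78.5% (16.0%, 57.6%, 67.8%, 64.0% and 89.0% unthinned). Each of these differed from its reference group in all 4 comparisons, with the mice taken as unpaired. The exact permutation p was 0.0079 in each, the smallest possible (0.0122 adjusted). Mki67 was found in 0.0638%, 3.74%, 3.65%, 2.06% and 3.06% (0.270%, 7.63%, 7.62%, 3.85% and 6.50% unthinned), with the same exact permutation p at the 3 days and 0.0952 for LRRC15+ against PDPN+ cells. Pdpn was found in 13.6%, 15.1%, 13.1%, 11.4% and 7.44% (41.3%, 43.7%, 38.3%, 31.8% and 20.4% unthinned). It was lower at day 24 than at day 0 (exact permutation p 0.0159) and lower in LRRC15+ cells (0.0079), and did not pass at day 7 (0.222) or day 14 (0.627). If hashtag numbers pair the mice of the day 24 libraries, 16 splits part all pairs, too few for a p under 0.05. The p-values for LRRC15+ against PDPN+ cells would not hold under that reading. For Lrrc15 the sort itself selects the difference. After thinning to 1000 UMIs, Lrrc15 at day 7 (0.0823 points above day 0, exact permutation p 0.405) and Pdpn at day 24 (−1.06 points, 0.119) did not pass. As background, Lrrc15 was found in none of 377 pericyte-like cells, which allows up to 0.796%, Cthrc1 in 3.45% and Pdpn in 0.796% of them, at a median depth of 5662 UMIs. Acta2 was found in 5.54% and Mki67 in 2.33% of 343 mesothelial-like cells (7932 UMIs), while the pools had median depths of 9277, 8857, 9854, 7494 and 6154 UMIs. The pericyte-like cells are pooled over all libraries, and before thinning only 28 of them came from day 0. The day 0 share of Cthrc1 lies below 3.45%, but whether it is background of the day 0 library was not tested. The Lrrc15 shares at day 0 and day 7 lie under the limit that 0 of 377 cells allows, so that a difference from background was not detectable for them at this depth. Mki67 was found in 0 of 107 mesothelial-like cells at day 0 and in 5 of 101 at day 7, so that these may cycle themselves, and no Mki67 share is read against them.

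**Figure D4:**
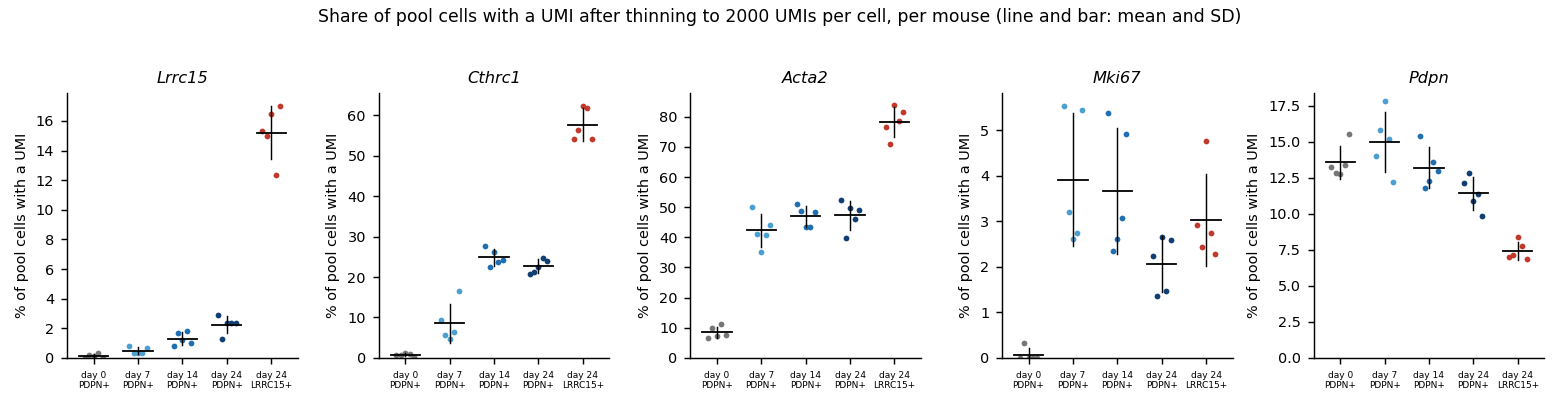
Share of fibroblast pool cells with a UMI of each gene (percent, axes starting at 0) after thinning to 2000 UMIs per cell, with 1 point per mouse and the mean and SD of 5 mice. Cthrc1 was found in 0.732 ± 0.358% of cells at day 0, 24.9 ± 2.09% at day 14 and 57.8 ± 4.04% in LRRC15+ cells.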

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

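The tests on the mix of clusters, on Cfd and the counts of other splits below were chosen only after the result was seen; the tests on free RNA and on clusters 1 and 5 were set beforehand.

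A single mouse stood far from the other 4 of its group in 8 of 130 groups of values screened, where chance alone gives about 1 in 20. In the day 0 library hashtag 10 had a Pdpn share of 15.51% against 12.8% to 13.4% in the others, and hashtag 7 had a Mki67 share of 0.333% and a mixed immune share of 0.294% against 0 in the others. In the day 7 library 3.93% of the cells of hashtag 7 were mesothelial-like against 1.42% to 2.08%, and hashtag 6 had Inmt at 72.7 CPM (186 to 247 in the others), Lsamp at 3.77 CPM (9.25 to 12.7) and Opcml at 2.09 CPM (8.40 to 13.2). In the LRRC15+ library hashtag 8 had a Mki67 share of 4.77% against 2.27% to 2.92%. Between day 7 and day 14 the effects against day 0 differed by a camera test of the step itself for fibrillar matrix genes (adjusted p = 0.0370 with an estimated correlation, up; 0.0648, 0.0865, 0.0591 and 0.0811 without hashtag 6, 7, 8 and 9), fibrotic fibroblast genes (0.0370, up; 0.0865 and 0.0811 without hashtag 7 and 9) and interferon response genes (0.00349, down). Outside the fibroblast pool, Saa3 stood at 790.6 ± 1094 CPM in mesothelial-like cells of day 7 (SD, n = 5 mice), where day 0 had no UMI. It was at least 201-fold higher against a floor of 3 counts over the group. This was at least 89.5-fold without hashtag 6 and 113-fold without hashtag 10. Its adjusted p of 0.013 was 0.0782 without hashtag 10. Whether free RNA of fibroblasts gave these UMIs was not tested.

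Chance as the source of the gene counts was tested by refitting 100 splits of each pair of groups. These fits hold only the 2 groups compared, unlike the counts from all groups given with the results. The real splits called 2247, 2683, 2514 and 1078 genes at day 7, day 14, day 24 and for LRRC15+ against PDPN+ cells. At the 3 days against day 0 the highest of the other splits called 0, so that only 1 split of 100 was as large. The real split thus stands apart from random groupings of the mice. Each other split mixes mice of both groups, so any large difference between the libraries would give this result, that of the lane included. These counts therefore cannot tell the source of the difference. For LRRC15+ against PDPN+ cells the hashtag numbers may pair the mice, which the labels do not say. If they do, 16 splits part all 5 pairs. The highest of the others among these called 0, but 16 splits are too few for a share under 0.05.

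The 616 genes at least 2-fold higher at day 14 than at day 0 had a median log2 ratio of 1.57 over the pool. If the changed mix of clusters were the whole source, they would be near 0 within cluster 7. Their median there was 0.84 (0.658 to 0.820 in single mice), with 562 of 616 higher, which argues against the mix as the whole source and leaves it open for a part. Free RNA of other day 14 cells could add to it and cannot be told apart, because the genes had a median log2 ratio of 0.96 UMIs per cell in cluster 7 over pericyte-like cells (0.353 to 1.42 in single mice), on either side of the bound of 1 set beforehand. An effect of bleomycin on these cells stays among the open explanations.

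The 24 genes lower in LRRC15+ than in PDPN+ cells of the fibrotic-like class may come from free RNA. Their median loss of UMIs per cell in cluster 3 was 1.12 times (1.124) that in the fibrotic-like class (quartiles 0.587 to 2.16), as free RNA of the day 24 PDPN+ library would give. If a different mix of clusters 1 and 5 were the whole source, these genes would be unchanged within each cluster. Their median log2 ratio was −1.32 within cluster 1 alone (−1.565 to −1.074 in single mice). Within cluster 5 it was −0.79 (−1.164 to −0.569 in single mice), against −1.51 for the class. The rule set beforehand asked for a median fall of more than 2-fold within both clusters to speak against the mix. Cluster 5 did not reach it, so that this test cannot tell. The values show only that these genes were lower within each cluster in every mouse taken alone. A true difference between LRRC15-sorted and other fibrotic-like cells stays open as well.

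Cfd had the lowest ratio from day 7 to day 14. A few adipocyte-like cells are a candidate source: 2 cells with at least 3 of the 4 markers held 99.34% of the 1664 Cfd UMIs of the day 7 pool, and without them 11 UMIs remained. The larger of the 2 had 1576 UMIs of Cfd, 416 of Car3 and 253 of Fabp4 among 21635, with 1 of Col1a1 and 0 of Pdgfra. Whether bleomycin changed their number was not tested.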

How the results depend on the processing

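The edgeR alternatives, the exact tests of shares and the replicate block were chosen only after the data were seen. So were the list tests with an estimated correlation and the list calls with a hashtag left out. The settings leaving out the contractile cluster or cluster 14 were chosen then too. Over all settings, counts by size stayed within 1.5 times for 215 of 240 values and edgeR counts for 191 of 194. No median of a list that passed (516 of 576 list medians within 1 SD) and no named gene (1359 of 1440 within 1 SD) turned its direction. Single named genes still moved on the log2 scale, by up to 4.43 without cycling cells and 2.30 over all filtered cells (medians 0.073 and 0.0335). The largest move was 2.08 when markers of each cell set the pool (median 0.02) and 0.427 without the contractile cluster. Of 102 list tests 66 kept their call, 34 lost it and 2 gained it. Of lists that did not pass, 11 medians took the other sign, in 5 lists and comparisons. Under TMM scaling these were endoplasmic reticulum genes at day 7 (0.01 to −0.02) and alveolar identity genes at day 14 (0.02 to −0.06). The count by size followed the floor on genes, by its construction. At 5 CPM it was 840 higher and 707 lower at day 7, 1073 and 849 at day 14, 958 and 729 at day 24 and 134 and 496 for LRRC15+ cells, and at 100 CPM 167 and 164, 226 and 223, 192 and 201, and 41 and 88. With other settings it was 360 to 485 higher at day 7, 518 to 640 at day 14, 464 to 566 at day 24 and 75 to 102 for LRRC15+ cells. From day 14 to day 24 edgeR called 157 genes lower over all filtered cells and 69 higher and 65 lower without hashtag 10 (main 132 and 99). It gave 1252 to 2246, 1354 to 2464, 1289 to 2268 and 277 to 424 genes higher in the same order for the main comparisons.

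With the stricter cell filter the mesothelial-like share at day 7 was 0.0927 points above day 0 (exact p 0.794) and its fall at day 14 −0.470 points (exact p 0.143), the mixed epithelial and endothelial share 0.01004 points above it at day 7 and 0.0116 at day 24, the mixed immune share −0.0161 for LRRC15+ minus PDPN+ cells, and the pool share −1.72 at day 14 (exact p 0.0079) and 0.0457 at day 24 (exact p 0.873). With several hashtags kept, the mixed immune share was 0.00145 points higher at day 24 and −0.0197 for LRRC15+ cells, and the Mki67 difference 1.42 points (exact p 0.0079). Other thinning depths moved 4 share calls: Lrrc15 at day 7 to 0.0823 points at 1000 UMIs (exact p 0.405), Pdpn at day 24 to −1.06 at 1000 UMIs (exact p 0.119), Pdpn at day 14 to −3.40 at 4000 UMIs (exact p 0.0476) and Mki67 in LRRC15+ cells to 1.85 at 4000 UMIs (exact p 0.0238). In the fibrotic-like class the replicate block gave 4 genes higher and 44 lower by at least 2-fold, and 662 and 620 of any size. Over the pool it gave 284 and 796, and 38 of 226 list members and named genes gained a call, 0 lost one and 0 of the genes named there changed; beside the list tests given with the results, it changed no other call of a list test. The cause of these changes was not tested. Scrublet marked at most 0.11% of cells in a library, and leaving out its calls left the size of each fibroblast pool unchanged. Depth limits the values within cluster 7, which rest on 165 to 473 cells a day.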

Other observations

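The genes and clusters here were chosen after their values were seen. Mesothelial-like cells, which were sorted along with the fibroblasts through PDPN, also differed between days. At day 7 against day 0 edgeR called 80 genes higher and 53 lower in them, of 2665 tested, and at day 24 it called 84 and 102, or 51 and 53 without hashtag 8 and 52 higher without hashtag 9. At day 7 the acute-phase gene Lcn2 rose from 19.8 ± 13.6 to 391 ± 305 CPM (SD, n = 5 mice; log2 ratio 4.08, edgeR adjusted p 5.5e-05), Timp1 from 56.9 ± 28.2 to 438 ± 185 (2.93) and Irf7 from 27.8 ± 26.9 to 213 ± 127 (2.87), and 6 of 9 interferon genes tested rose. The insulin-like growth factor binding protein Igfbp6 fell from 5404 ± 604 to 1724 ± 361.5 CPM and Fxyd3 by 2.43 on the log2 scale. At day 24, 11 of 13 matrix genes tested rose, against 3 at day 7 and 6 at day 14. These were 7 without hashtag 9 or 10 at day 24, 1 without hashtag 7, 9 or 10 at day 7 and 3 without hashtag 7 at day 14. The basement membrane collagen Col4a2 rose from 33.9 ± 4.87 to 268 ± 185. Gsta3, a glutathione transferase, fell to 285 ± 150 CPM. These sums rest on 64 to 108 cells a day, and the difference between the days was not tested. Several hashtags were called on 15.3% of the mesothelial-like barcodes, and doublets of cells from the same mouse remain. Saa3, Lcn2, Timp1, Irf7 and most matrix genes rose in the fibroblast pool as well. Whether free RNA of fibroblasts or such doublets gave these values was not tested.

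Within the alveolar-like class (cluster 0), which was rare at day 0, edgeR called 220 genes higher and 177 lower at day 14 against day 7. Igfbp2 rose from 0.572 ± 0.878 to 131 ± 25.9 CPM (log2 ratio 6.16, adjusted p 2.7e-09), Fmod from 33.8 ± 18.9 to 314 ± 32.2, the matrix protein periostin (Postn) from 18.4 ± 11.6 to 170 ± 36.3 (2.95) and Thbs2 from 5.65 ± 3.58 to 50.7 ± 8.49 (2.76). Cxcl13 fell from 163.5 ± 96.0 to 6.74 ± 6.44 CPM (−4.39), Has1, a hyaluronan synthase, from 127 ± 10.3 to 25.7 ± 13.1 (−2.14) and Irf7 from 109.6 ± 50.4 to 24.1 ± 6.53 (−2.03). In the fibrotic-like class, 252 genes were called higher and 115 lower at day 24 against day 14. This mixes a change of clusters with change within them, since cluster 1 held 186 of its cells at day 14 and 753 at day 24, and cluster 5 held 298 and 225. Within cluster 1 edgeR called 61 higher and 38 lower, and within cluster 5 it called 38 (25 without hashtag 10) and 22. Over the class, the Wnt modulator Sfrp2 rose from 8.16 ± 3.44 to 73.8 ± 24.1 CPM (adjusted p 7.1e-08), Abi3bp from 39.9 ± 21.9 to 192 ± 59.1 (2.32) and the cartilage protein Comp from 2.16 ± 0.735 to 17.9 ± 6.09 (2.56). The epithelial checkpoint protein gene Sfn, the first top gene of cluster 5, fell from 86.1 ± 16.8 to 18.6 ± 6.24 CPM (−2.15), and Angptl4 from 184 ± 57.8 to 39.2 ± 22.9 (−2.31). Within cluster 1, edgeR log2 folds were 2.27 for Sfrp2 (adjusted p 4.0e-05), 1.32 for Abi3bp, 2.05 for Comp and −2.50 for Angptl4, and Sfn was too low to be tested. Within cluster 5, Sfn fell from 116.5 ± 11.3 to 49.5 ± 16.4 CPM (edgeR log2 fold −1.29, adjusted p 1.9e-04) and Angptl4 by 1.80 on the log2 scale. Sfrp2 had an adjusted p there of 0.016, and 0.086 and 0.0586 without hashtag 8 and 10, and Abi3bp of 0.033, and 0.108, 0.182 and 0.181 without hashtag 6, 7 and 10. Of 12 Wnt genes 8 rose and 2 fell over the class, 4 and 1 of 12 within cluster 1, and 2 and 1 of 10 within cluster 5.

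Some clusters came mostly from 1 library and can be a state of that library. Cluster 4, led by Sbspon, Cnn1, Ibsp and Myh11, held 1654 LRRC15+ cells of 1 hashtag against 302 day 24 PDPN+ cells. Over all 2343 of its barcodes, those with several hashtags included, Lrrc15 was found in 40.7%. Cluster 18, led by the cartilage and tendon genes Wif1, Chad and Acan, had 377 barcodes counted the same way, of which 227 were LRRC15+ and 32 day 0, with Lrrc15 found in 53.1% at a median depth of 5913 UMIs. Cluster 14 held 489 day 7 barcodes of 522 on the same count, at a median of 6.66% mitochondrial UMIs.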
